A study of Homo sapiens with 20 samples.

How the data were processed

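Labelled RNA was measured in 20 libraries of H1299 cells, 2 for each of 10 groups: WT or K512R PABPC1, at 0 h, at 3 and 6 h of chase, and at 3 and 6 h of chase with arsenite. Per the labels' protocols, RNA carrying 4sU was coupled to HPDP-biotin, captured on streptavidin, depleted of ribosomal RNA and made into stranded total RNA libraries. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.3 and aligned to hg19 with HISAT2 2.0.4. The counting tool and the scaling were not given in the sources used here.

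The deposited values are a signal per gene or transcript: per the file headers they are counts, but they hold fractions and add up to nearly the same total in each library, so they were treated as estimated counts scaled to a common library size. In each library the low values step by a fixed amount, the worth of a single read, from 0.6977 to 1.7228 scaled counts. A share of 88.8 to 91.5% of protein-coding values and 58.3 to 63.7% of lncRNA values were whole multiples of that amount, within 0.02 reads. The other values were taken to hold reads divided between genes or transcripts, so that whole reads were not recovered and tests for raw counts were not used. At high levels a fixed 0.02 reads is a strict bar. MKI67, in a locus of its own, passed it in only 7 libraries. The design, written before the data were examined, had assumed counts, FPKM or another normalized value, and the test for normalized values was used.

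Per library, 12414 to 13878 protein-coding genes had a value above 0. Protein-coding values were summed per gene symbol (20308 rows, 20233 symbols, 74 of them with more than 1 row), while lncRNAs were kept as 37684 transcripts, whose values added up to 0.9 to 1.06 M (mega) per library. Kept for testing were 15028 genes with at least 1 scaled count in at least 2 libraries and 11450 transcripts with at least 0.5 in at least 2. Of the genes tested, 6213 (41.3%) share their locus with another gene and 12172 (81%) had whole-read values in all 20 libraries. Of the transcripts tested, 2444 overlap exons of another gene on the same strand, and all lie in 6098 loci. Coordinates are those of the files, 1-based on hg19.

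Log2(value + 0.5) was fitted with limma 3.58.1 (in R 4.3.3, with data.table at version 1.17.8) with a mean for each of the 10 groups, a trended prior variance and 10 residual degrees of freedom. Every log2 value in the text is on this scale, so that fold changes of low genes are drawn toward 0, and values for genes listed at 0 in a whole group, where given, are fitted values with no bound. P-values were adjusted by Benjamini and Hochberg within each comparison, and a call is an adjusted p under 0.05. Comparisons were K512R against WT at 0 h, the chase in each line, arsenite against no arsenite at the same time in each line, and the difference between the lines in the chase, in the arsenite chase and in the effect of arsenite. Direct comparisons of the lines at the other times and of the arsenite chase with 0 h were made besides. The 95% interval of a gene reached 0.83 log2 units to each side in the median for pairs of groups and 1.17 for differences between the lines (lncRNA 3.27 and 4.62).

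Gene lists were written from general knowledge before the data were examined. For protein-coding genes they were mitophagy, autophagy core machinery, heat shock response, metallothioneins, NRF2 targets, integrated stress response targets, immediate early and AU-rich element mRNAs, ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded, glycolysis, replication-dependent histones, zinc finger ZNF genes, G2/M cell cycle, stress granule components, PABP and SUMO pathway, mRNA decay machinery, cholesterol synthesis, secretory pathway and extracellular matrix, and haematopoietic, fibroblast, endothelial and hepatocyte markers. For lncRNAs they were snoRNA host, nuclear and cytoplasmic lncRNAs, with each tested transcript of a listed gene counted as a member. Lists with at least 5 tested members were tested against all other genes with camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with a correlation estimated from the data, with fry beside it. Calls of members were also adjusted over the list alone.

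Named genes followed a rule written before the data were examined. They are PABPC1, the 5 called genes with the largest rises and the 5 with the largest falls (4 and 4 for lncRNA) among those with at least 20 scaled counts in a group and libraries wholly apart, and, per list, 2 to 4 called members with the largest change, or the 2 with the highest mean where none was called. Genes that sit in shared loci or have near-identical copies keep an uncertain share of reads.

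The fit was tested on simulated reads, drawn for each gene from its real mean over all 20 libraries and its real residual spread. In a single group, 50 genes each, with a mean of at least 20 scaled counts, were changed by 1.5, 2, 4 or 8-fold. For the WT arsenite comparison at 6 h 10, 40, 72 and 94% of them were recovered, for K512R against WT at 0 h 8, 40, 76 and 74%, and for the genotype by arsenite contrast 4, 28, 54 and 74%. For the lncRNA arsenite comparison the shares were 0, 0, 8 and 6%. Of the calls made on simulated data, 6.9% in the WT arsenite comparison, 5.3% in the WT chase at 6 h, 2.9% in K512R against WT at 0 h and 7% in each of 2 genotype contrasts were false. A list of 30 genes shifted by 0.5 log2 units was called in all 5 comparisons tested, and 0 of 20 other lists were. Because reads were drawn gene by gene, the simulated lists held no correlation between genes. The absence of calls among the other lists therefore cannot show whether the preset correlation of 0.01 is high enough for the real data.

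Alternatives tried were pseudocounts of 0.1 and 1, no filter on low values, quantile normalization, the replicate number as a block, a fit of only the libraries compared, each library left out in turn, and single rows in place of sums per symbol. Added after the data were seen were a filter at 20 scaled counts, library quality weights, only genes in a locus of their own, lncRNA values summed per locus, and lncRNAs without those overlapping exons on the same strand. The planned test of 3′ UTR uridine content was left out because it needs a genome sequence, which was not used here.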

Results

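The study followed labelled RNA in H1299 cells, an established human lung carcinoma line, that stably expressed a Myc-tagged poly(A)-binding protein, PABPC1. One line carried the wild-type protein (WT) and the other a lysine-to-arginine substitution named K512R. The series title concerns SUMOylation of PABPC1, stress granules, U-rich mRNAs and mitophagy. Cells took up 4-thiouridine (4sU), a uridine analogue that is built into newly made RNA, for 2 h. The medium was then exchanged for fresh medium, to which sodium arsenite (500 µM), an oxidative stressor that induces stress granules, was added in some of the groups. RNA was collected at 0, 3 or 6 h of this chase, and the labelled RNA was biotinylated, captured, depleted of ribosomal RNA and sequenced. The libraries whose titles carry the letters AS were taken as those with arsenite. Together these made 10 groups of 2 libraries: each line at 0 h, at 3 and 6 h, and at 3 and 6 h with arsenite.

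Values are read counts per gene or per long non-coding RNA (lncRNA) transcript that had been scaled to a common library size, here called scaled counts. They give each RNA's share of the captured pool and not an absolute amount, because no spike-in was used here. A gene whose RNA is lost more slowly than the rest of the pool, or is added to it, therefore rises in scaled counts during a chase. Protein-coding values added up to 10.83 to 10.99 M scaled counts per library. The worth of a single read, recovered from the low values, placed the protein-coding depth at a median of 11 M reads. The lowest was 6.31 M (K512R with arsenite at 6 h, replicate 1) and the highest 15.67 M (WT at 6 h, replicate 1). Replicates correlated with a Spearman rho of 0.962 to 0.987 across genes. The lowest rho was that of K512R with arsenite at 6 h. The largest median absolute difference between replicates was that of K512R at 6 h, 0.338 log2 units over 9381 genes against 0.144 to 0.276 in the other groups. Every mean ± SD below is over 2 libraries. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

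PABPC1 itself (ENSG00000070756, hg19 chromosome 8, 101698044 to 101735037, minus strand) was measured in both lines. At 0 h it stood at 14342 ± 2099 scaled counts in WT and 14905 ± 351 in K512R cells, a log2 difference of 0.06 (SE 0.12, limma adjusted p = 1). Without arsenite it went down during the chase, to 9753 ± 1383 in WT (log2 change −0.56, adjusted p = 0.0027) and 9649 ± 625 in K512R cells at 6 h (−0.63, adjusted p = 0.00099). With arsenite it reached 36883 ± 1847 in WT and 34935 ± 2083 in K512R cells at 6 h, against the untreated 6 h libraries a log2 difference of 1.93 (SE 0.12, adjusted p = 1.7e-09) and 1.86 (adjusted p = 2.5e-09). None of the 4 contrasts of the response between the lines passed the test for PABPC1, with log2 values from −0.14 to −0.07 (SE 0.17). The WT fall missed the threshold without WT 0 h replicate 1 (adjusted p = 0.052) or WT 6 h replicate 2 (0.053). Gene-level values do not separate the introduced from the endogenous PABPC1 mRNA or show the K512R base change, and PABPC1 reads can be shared with its retrocopy PABPC3.

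**Figure D1:**
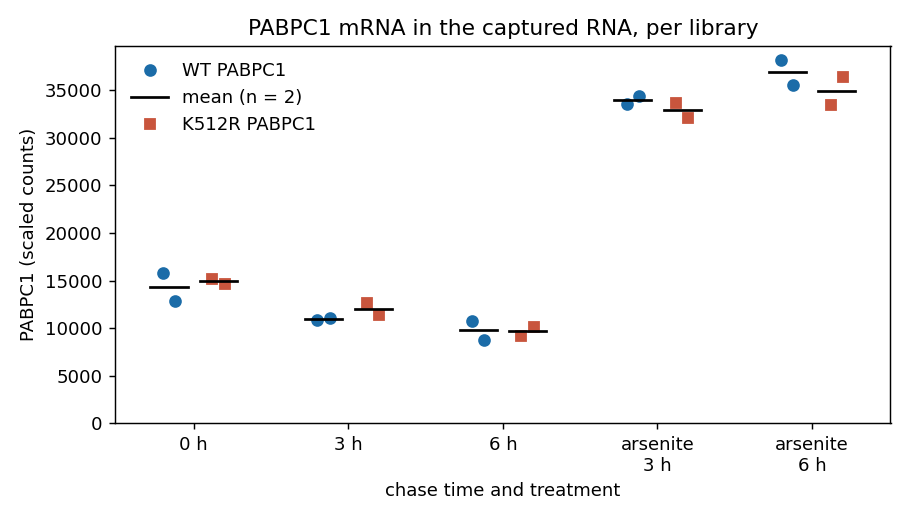
PABPC1 in scaled counts (vertical axis) in each of the 20 libraries, by chase time and treatment (horizontal axis), with circles for WT, squares for K512R and a black line for the mean of 2 libraries. All libraries with arsenite lie between 32128 and 38190 scaled counts, above all libraries without it (8775.4 to 15826).

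Which mRNAs differed between the lines at the end of the pulse, before any chase or stress, was asked by comparing K512R with WT at 0 h. No protein-coding gene passed the test. SQSTM1, an autophagy receptor with the highest mean of the mitophagy list over all 20 libraries, stood at 12000 ± 678 scaled counts in K512R and 10800 ± 1650 in WT cells (log2 difference 0.15, SE 0.18). HUWE1, a ubiquitin ligase of the same list, stood at 12000 ± 736 and 11100 ± 97.9 (0.11, SE 0.11). G3BP1, a core protein of stress granules, stood at 13900 ± 162 and 12600 ± 355 (0.14, SE 0.10), and the mitochondrial MT-CO1 at 84500 ± 4580 and 84400 ± 15800 (0.01, SE 0.14). Of 15028 genes, limma called 0 at an adjusted p under 0.05, and 456 had an unadjusted p under 0.05, against 751 by chance. Without K512R 0 h replicate 2 it called 9. The fit takes the same spread for a gene in all 10 groups. Yet the median replicate difference was 0.214 in WT and 0.203 in K512R at 0 h, against 0.338 in K512R at 6 h. The count of 456 may thus reflect a spread too wide for the 0 h groups, which these values do not settle. Direct comparisons of the lines also stayed under 751 at 3 h (593), at 6 h (600) and with arsenite at 3 h (462). With arsenite at 6 h the count was 1490. The 6 h comparison holds the group with 0.338, so the shortfall was not particular to 0 h. Neither the mitophagy list (39 genes, median 0.05, camera adjusted p = 0.6) nor the stress granule list (35 genes, median 0, adjusted p = 0.96) differed from the other genes. Integrated stress response targets were shifted upward by a median of 0.18 (adjusted p = 0.011) with 0 of 20 members called, also when adjusted over the list alone. That shift had an adjusted p = 0.99 with an estimated correlation, and an adjusted p = 0.71 without WT 0 h replicate 1, 0.069 without K512R 0 h replicate 1 and 0.12 without K512R 0 h replicate 2. The median 95% interval of a gene reached 0.83 log2 units to each side. Of simulated 2-fold changes, in genes with a mean of at least 20 scaled counts, 40% were recovered in this comparison.

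During the first 3 h of chase without arsenite in WT cells, some mRNAs rose and others fell relative to the rest of the captured pool. ERRFI1, an inhibitor of EGF receptor signalling, went from 3640 ± 137 to 10400 ± 46.4 scaled counts (log2 change 1.51, SE 0.11, limma adjusted p = 2.3e-06). The growth factor FGF5 went from 1810 ± 111 to 6060 ± 90 (1.74, SE 0.16, adjusted p = 2e-05). The matrix glycoprotein THBS1 went from 1820 ± 61.1 to 4410 ± 13.2 (1.27, SE 0.12, adjusted p = 2e-05) and STC1 from 401 ± 4.5 to 1120 ± 194 (1.46, SE 0.21, adjusted p = 0.0013). Histone mRNAs fell, with HIST1H2BG at 166 ± 19.6 against 553 ± 85.5 (−1.73, SE 0.26, adjusted p = 0.0017). The ribosomal protein mRNA RPL14 fell as well, to 1370 ± 166 from 2470 ± 174 (−0.86, SE 0.12, adjusted p = 0.0015).

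Of the 15028 genes, 400 were called at 3 h, 233 higher and 167 lower. Replication-dependent histones had 20 of 50 members lower (35 when adjusted over the list alone, median −1.42, camera adjusted p = 1.8e-25, adjusted p = 0.038 with an estimated correlation). Ribosomal proteins had 19 of 78 lower (66 adjusted over the list alone, median −0.65, adjusted p = 2.4e-37, but adjusted p = 0.074 with an estimated correlation). Among the mitochondrially encoded mRNAs, 6 of 12 were lower (8 adjusted over the list alone, median −0.55, adjusted p = 0.038 with an estimated correlation). Zinc finger ZNF genes had 11 of 448 lower (15 adjusted over the list alone, median −0.26, adjusted p = 0.00094 with an estimated correlation). The nuclear-encoded respiratory chain had 6 of 75 lower (17 adjusted over the list alone, median −0.57, camera adjusted p = 1e-13, adjusted p = 0.12 with an estimated correlation). The Wnt inhibitor DKK1 was also among the largest rises (18.6 ± 18.8 to 169 ± 46.1, adjusted p = 0.018), and DLX2, HIST1H2AI, HIST3H2A and CHST9 among the largest falls. Each of these 5 calls was lost when single libraries were left out (highest adjusted p from 0.12 for HIST3H2A to 0.42 for HIST1H2AI). The count itself went from 400 to 181 and 93 without WT 0 h replicate 1 or 2, and to 49 and 51 without WT 3 h replicate 1 or 2. It was 753 in a fit of the 4 libraries alone and 1421 with library quality weights.

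By 6 h of chase without arsenite in WT cells, histone mRNAs, zinc finger factors, mitochondrially encoded mRNAs and immediate early regulators had fallen relative to the rest of the pool. Ribosomal proteins were lower in 75 of 78 genes, though with an adjusted p = 0.053 with an estimated correlation. RPS28, a protein of the small ribosomal subunit, fell from 806 ± 84.6 to 207 ± 116 scaled counts (log2 change −2.08, SE 0.30, limma adjusted p = 0.00011). The histone mRNA HIST1H2AL (hg19 chromosome 6, 27833034 to 27833606, plus strand) fell from 771 ± 82.1 to 101 ± 13.3 (−2.92, SE 0.26, adjusted p = 1.4e-06). ZNF57, a zinc finger factor, fell from 341 ± 43.7 to 34.9 ± 18.7 (−3.37, SE 0.35, adjusted p = 4.5e-06). The mitochondrial MT-ND1 fell from 59700 ± 15900 to 23400 ± 1920 (−1.33, SE 0.14, adjusted p = 7.3e-06). In the other direction, mRNAs of mitotic proteins such as ECT2, which acts in cytokinesis, rose from 3430 ± 182 to 6210 ± 444 (0.86, SE 0.13, adjusted p = 0.00018).

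Ribosomal proteins were the most uniform group, with 75 of 78 measured members lower, 0 higher and 3 not called (76 lower when adjusted over the list alone, median −1.04, camera adjusted p = 3.1e-34, though adjusted p = 0.053 with an estimated correlation). RPL24 went from 2510 ± 703 to 813 ± 359 (log2 change −1.67, SE 0.28). Of 50 replication-dependent histones 36 were lower (38 adjusted over the list alone, median −2.24, adjusted p = 0.033 with an estimated correlation). Of 448 zinc finger ZNF genes 207 were lower and 3 higher (243 and 4 adjusted over the list alone, median −0.87, adjusted p = 8e-07 with an estimated correlation). The nuclear-encoded respiratory chain had 32 of 75 lower and 2 higher (41 and 2 adjusted over the list alone, median −0.85, adjusted p = 1.6e-09, but adjusted p = 0.16 with an estimated correlation). Among them were the ATP synthase subunit ATP5E (942 ± 102 to 270 ± 72.7) and the cytochrome oxidase subunit COX4I1 (2290 ± 358 to 840 ± 247). Mitochondrially encoded mRNAs had 8 of 12 lower (9 adjusted over the list alone, median −1.02, adjusted p = 0.032 with an estimated correlation). Their genes overlap each other in part, so the split of reads between them is uncertain.

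Immediate early and AU-rich element mRNAs, a class known for fast turnover, had 19 of 35 members lower and 1 higher (22 and 2 adjusted over the list alone, median −1.19, adjusted p = 0.0081 with an estimated correlation). The transcription factor JUNB went from 281 ± 60.4 to 27.5 ± 8.3 (log2 change −3.34, SE 0.61, limma adjusted p = 0.00083) and FOS from 110 ± 22.9 to 6.79 ± 5.66 (−4.16, SE 0.87, adjusted p = 0.0025, or 0.056 without WT 6 h replicate 1). Integrated stress response targets had 10 of 20 lower and 3 higher (11 and 3 adjusted over the list alone, median −0.6, adjusted p = 0.018). That call was lost with an adjusted p = 0.48 with an estimated correlation, 0.12 in a fit of only the 4 libraries compared and 0.081 without WT 0 h replicate 2. Its PPP1R15A, a phosphatase subunit that ends the response, went from 979 ± 312 to 213 ± 10.6 (−2.16, SE 0.22), and SESN2 from 459 ± 176 to 110 ± 50.6. The G2/M cell cycle list had 15 of 32 higher and 0 lower (16 and 0 adjusted over the list alone, median 0.40, adjusted p = 0.00042 with an estimated correlation). Among them were KIF11 (3610 ± 448 to 5470 ± 229) and TOP2A (6680 ± 473 to 9740 ± 412).

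Stress granule components had 10 of 35 higher and 5 lower (12 and 6 adjusted over the list alone). LARP4 rose from 3680 ± 166 to 6130 ± 405, whereas HNRNPA1 fell from 18100 ± 2910 to 9770 ± 1310. The list's median of 0.04 (adjusted p = 0.023, and adjusted p = 0.047 with an estimated correlation) became −0.10 with quantile normalization (adjusted p = 0.88). The call was also lost in a fit of only the 4 libraries (0.059), over genes in a locus of their own (0.16) and without WT 6 h replicate 1 (0.063). Members of the mitophagy list moved both ways, with 5 of 39 higher and 4 lower, likewise when adjusted over the list alone (median 0.08, mean −0.14, adjusted p = 0.15). The mitochondrial ubiquitin ligase MUL1 (437 ± 56.1 to 158 ± 8.34, log2 change −1.46, SE 0.25, limma adjusted p = 0.00058) and the import subunit TOMM7 (558 ± 56.9 to 188 ± 4.02, −1.56, SE 0.30, adjusted p = 0.0011) fell. The mitochondrial transport GTPase RHOT1 went from 290 ± 24.7 to 565 ± 32.1 (adjusted p = 0.04, but 0.1 to 0.19 without any 1 of its 4 libraries).

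Other lists were not called, though single members changed. Autophagy core machinery had 2 of 38 higher and 1 lower (adjusted p = 0.22), with LAMP2 at 1600 ± 289 against 956 ± 39.6 and ATG16L1 at 421 ± 15.8 against 742 ± 161 (lost without WT 6 h replicate 1, adjusted p = 0.11 and 0.053). Heat shock response genes had 2 of 23 higher and 7 lower (median −0.12, adjusted p = 0.49), with the chaperone DNAJB1 down from 3260 ± 648 to 1480 ± 276. Metallothioneins had 2 of 5 lower (adjusted p = 0.22), with MT1X down from 254 ± 70.6 to 86.1 ± 0.388. NRF2 targets had 3 of 26 higher and 4 lower (adjusted p = 0.84), with GCLM up from 1830 ± 153 to 3170 ± 228 and TXN down from 1910 ± 96.1 to 1150 ± 52. Glycolysis had 5 of 18 lower (median −0.31, adjusted p = 0.12, but 0.01 with quantile normalization and 0.028 without WT 0 h replicate 1). The list of mRNA decay machinery had 4 of 43 higher and 9 lower (adjusted p = 0.83), with the deadenylation factor TOB2 down from 1280 ± 239 to 452 ± 22.7. Cholesterol synthesis had 1 of 22 higher and 4 lower (adjusted p = 0.2), with INSIG1, which holds back sterol synthesis, down from 3070 ± 140 to 1060 ± 152. The secretory pathway and extracellular matrix list had 4 of 26 higher and 1 lower (adjusted p = 0.17), with THBS1 up from 1820 ± 61.1 to 5280 ± 324. The PABP and SUMO pathway list had 2 of 26 higher and 3 lower (adjusted p = 0.21). As to markers of other cell types, none of the 5 haematopoietic, 6 fibroblast, 3 endothelial and 3 hepatocyte markers tested was called. CD68 stood at 197 ± 11.7 scaled counts at 6 h and 211 at 0 h, and FAP at 11 and 10.9.

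Over all genes, limma called 2693 of 15028 in the WT 6 h chase, 995 higher and 1698 lower, of which 1103 changed at least 2-fold. The median gene changed by −0.16, a shift that quantile normalization removes (1043 higher and 1208 lower). List tests are against the other genes, yet some moved with that normalization as well, as those of stress granule components and glycolysis did. The count fell to 1487 without WT 0 h replicate 2 and to 1498 without WT 6 h replicate 1, and was 1682 over genes in a locus of their own. The largest single changes were mostly genes in shared loci or with fractional values, whose reads the counting had to divide. ZCCHC3 went from 194 ± 75 to 1.51 ± 2.14 (−7.14, SE 0.88, adjusted p = 2.6e-05). VNN1, MTFP1, CTC-487M23.8 and CSNK2B-LY6G5B-1181 went to about 0 from 39.4 to 106 scaled counts. In the other direction GATS, RP11-598P20.5 and LST3 came up from about 0 to 25.8 to 74.7. DKK1 (18.6 ± 18.8 to 108 ± 13.7, adjusted p = 0.011) and TSPAN13 (50.6 ± 33.1 to 160 ± 25, adjusted p = 0.032) rose as well. Apart from ZCCHC3, each of these calls was lost without at least 1 library (highest adjusted p from 0.054 for CTC-487M23.8 to 0.34 for TSPAN13).

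**Figure D2:**
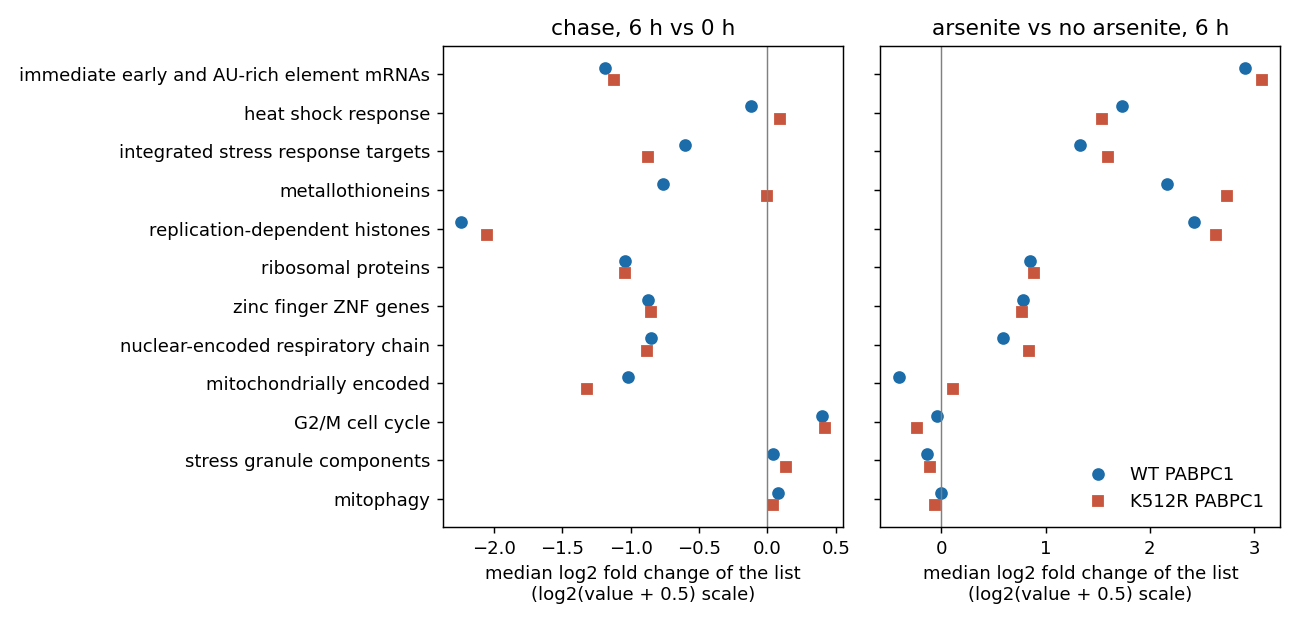
Median log2 fold change (horizontal axes, log2(value + 0.5) scale) of the genes of 12 lists (vertical axis) in the 6 h chase (left) and with arsenite against without at 6 h (right), with circles for WT and squares for K512R. Histone medians are −2.24 and −2.05 in the chase and 2.42 and 2.64 with arsenite. The WT chase median of stress granule components (0.04) turns to −0.10, the WT arsenite median of the G2/M list (−0.04) to 0.05 and the K512R arsenite median of the mitophagy list (−0.06) to 0 with quantile normalization.

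The same chase in K512R cells showed histone, mitochondrially encoded and zinc finger mRNAs falling relative to the rest. Ribosomal proteins were lower in 76 of 78 genes, with an adjusted p = 0.068 with an estimated correlation. MT-ND1 went from 55800 ± 2550 to 19700 ± 465 scaled counts (log2 change −1.50, SE 0.14, limma adjusted p = 2.3e-06). The acidic ribosomal protein RPLP1 went from 4880 ± 92.6 to 1840 ± 1250 (−1.59, SE 0.29, adjusted p = 0.00084) and the histone HIST1H3F from 432 ± 62.1 to 48.1 ± 50.5 (−3.71, SE 0.56, adjusted p = 0.00016). ZFP36, which binds AU-rich elements, fell from 351 ± 19.5 to 57.5 ± 14.1 (−2.62, SE 0.23, adjusted p = 1.1e-06), and the mitotic DLGAP5 rose from 976 ± 129 to 1990 ± 308 (1.02, SE 0.15, adjusted p = 0.00011).

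By list, 76 of 78 ribosomal proteins were lower in the K512R chase (77 adjusted over the list alone, median −1.04, camera adjusted p = 1e-30, adjusted p = 0.068 with an estimated correlation). So were 36 of 50 histones (37, median −2.05, adjusted p = 0.036 with an estimated correlation) and 10 of 12 mitochondrially encoded mRNAs (10, median −1.32, adjusted p = 0.012 with an estimated correlation). ZNF genes had 198 lower and 5 higher (231 and 7 adjusted over the list alone, median −0.85, adjusted p = 2e-06 with an estimated correlation). The respiratory chain had 40 of 75 lower (48 and 1 higher, median −0.88, adjusted p = 0.12 with an estimated correlation). Of the immediate early and AU-rich element list 19 of 35 were lower (24 and 2 higher, median −1.12, adjusted p = 0.0086 with an estimated correlation). G2/M genes were higher in 15 of 32 and lower in 1 (17 and 2 adjusted over the list alone, median 0.42, adjusted p = 0.00033 with an estimated correlation). Stress granule components had 11 of 35 higher, such as G3BP2 (4180 ± 43.4 to 7410 ± 693), and 6 lower. That list's call (median 0.14, adjusted p = 0.0061) was lost with quantile normalization (adjusted p = 0.76). Mitophagy genes had 9 of 39 higher and 7 lower (9 and 8 adjusted over the list alone, median 0.04, adjusted p = 0.26, but 0.045 without K512R 6 h replicate 2), with MUL1 down from 465 ± 70.4 to 184 ± 58.

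In all, 3074 genes were called in the K512R chase, 1091 higher and 1983 lower (1152 and 1218 with quantile normalization, which removes a shift of −0.15 in the median gene). Both lines together had 751 genes called higher in each (72 by chance for independent lists) and 1260 called lower in each (224 by chance), and 2 in opposite directions. The chance values take every gene as equally likely to be called. Both lists used the same estimate of each gene's spread, so these values may be too low. The lines share no libraries, and their log2 changes correlated across genes at r = 0.33 over all genes and 0.77 over the 9381 with a mean of at least 100, genes not being independent replicates. Replicate 2 of the K512R 6 h group stood far from all other libraries on the second principal component (−118.7 against 5.3 for replicate 1), and without it 1527 genes were called. Its ribosomal proteins stood below those of replicate 1 by a median of 0.65 log2 units and its histones by 0.52. Without K512R 0 h replicates 1 or 2 the counts were 1718 and 2044, in a fit of the 4 libraries alone 1174, and over genes in a locus of their own 1913. The genes with the largest rises and falls were low or in shared loci (for example LEKR1, 2.25 ± 3.19 to 35.3 ± 10.1, adjusted p = 0.013, or 0.18 without K512R 0 h replicate 1). GPR146 (37.6 ± 10.6) and PATE2 (35 ± 25.7) at 0 h were listed at 0 at 6 h, calls lost in the fit of the 4 libraries alone (adjusted p = 0.062 and 0.084).

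What arsenite changed in the WT labelled pool was asked against the untreated chase of the same length, first at 3 h. FOS, an immediate early transcription factor, stood at 13900 ± 1230 scaled counts with arsenite and 45.6 ± 16.1 without (log2 difference 8.28, SE 0.87, limma adjusted p = 4.1e-06), and EGR1 at 27500 ± 1450 against 209 ± 23.6 (7.04, SE 0.37, adjusted p = 7.7e-10). The inducible HSP70 gene HSPA1A reached 9020 ± 1690 against 325 ± 39 (4.79, SE 0.20, adjusted p = 4.4e-11). The metal-binding MT1X reached 4270 ± 343 against 196 ± 42 (4.45, SE 0.23, adjusted p = 4.4e-10) and the haem oxygenase HMOX1 2310 ± 332 against 233 ± 10.4 (3.29, SE 0.42, adjusted p = 2.8e-05). The mitochondrial MT-CO3 was lower, at 7980 ± 456 against 17100 ± 175 (−1.10, SE 0.13, adjusted p = 1e-05).

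At 3 h, 29 of 35 immediate early and AU-rich element mRNAs were higher with arsenite and 0 lower (29 adjusted over the list alone, median 2.13, adjusted p = 5.1e-05 with an estimated correlation). So were 19 of 23 heat shock genes, with 1 lower (20 and 1, median 1.36, adjusted p = 0.00031 with an estimated correlation) and 13 of 20 integrated stress response targets (15, median 1.24, adjusted p = 0.02 with an estimated correlation). Histones had 28 of 50 higher (34, median 1.36, adjusted p = 0.046 with an estimated correlation), such as HIST1H2BN (1080 ± 131 against 246 ± 30.3). Of 12 mitochondrially encoded mRNAs 9 were lower (9 adjusted over the list alone, median −0.67, adjusted p = 0.029 with an estimated correlation). Mitophagy genes had 2 higher and 5 lower (3 and 5, adjusted p = 0.63), and G3BP1 of the stress granule list was lower at 11700 ± 289 against 17700 ± 189. RASD1, HSPA6, C1orf61 and FOSB were with FOS the 5 largest rises, by 8.28 to 9.43 log2 units. The 5 largest falls, PALM2-AKAP2, FP15737, HOXB13, ST6GALNAC5 and PCDHA9, were each lost without at least 1 library (highest adjusted p from 0.061 to 0.2). There were 1922 calls, 943 higher and 979 lower, and 962 to 1249 when any 1 of the 4 libraries was left out (962 without WT 3 h replicate 2). A fit of the 4 libraries alone gave 2938 and library quality weights 3282.

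At 6 h, stress-induced mRNAs had the largest differences between WT cells with and without arsenite. FOS stood at 14100 ± 401 scaled counts against 6.79 ± 5.66 without arsenite (log2 difference 11.18, SE 0.87, limma adjusted p = 3.4e-08). HSPA6, an inducible HSP70 gene, stood at 4830 ± 4.43 and was listed at 0 in both untreated 6 h libraries, as were RASD1 (696 ± 79.2 with arsenite), the chemokine receptor CXCR4 (598 ± 19.8) and C1orf61 (574 ± 180). DDIT3, which encodes the stress transcription factor CHOP, reached 2520 ± 304 against 72.4 ± 15 (5.12, SE 0.26, adjusted p = 1.4e-10). HSPA1A reached 9110 ± 506 against 312 ± 41 (4.87, SE 0.20, adjusted p = 1.1e-11) and MT1X 5680 ± 199 against 86.1 ± 0.388 (6.04, SE 0.23, adjusted p = 6e-12). Reads of HSPA1A and its near-identical copy HSPA1B (10000 ± 710 against 203 ± 50.2) may be shared, as may those of the metallothioneins.

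Of the stress lists, immediate early and AU-rich element mRNAs had 33 of 35 members higher and 0 lower (34 adjusted over the list alone, median 2.91, camera adjusted p = 6e-31, adjusted p = 6.8e-05 with an estimated correlation). EGR1 stood at 22800 ± 453 against 116 ± 55.4 and EGR2 at 1680 ± 51.6 against 3.49 ± 4.93. Heat shock genes had 21 of 23 higher and 1 lower, likewise when adjusted over the list alone (median 1.73, adjusted p = 0.0023 with an estimated correlation). Integrated stress response targets had 14 of 20 higher and 0 lower (14 adjusted over the list alone, median 1.33, adjusted p = 8.7e-09, but adjusted p = 0.074 with an estimated correlation). Among them were PPP1R15A (4550 ± 64.6 against 213 ± 10.6), CHAC1 (475 ± 72.4 against 19.7 ± 11) and SESN2 (1060 ± 222 against 110 ± 50.6). Of the 26 NRF2 targets, which guard against oxidative stress, 9 were higher and 2 lower (10 and 2 adjusted over the list alone, median 0.46, adjusted p = 0.017, but adjusted p = 0.25 with an estimated correlation and 0.081 without WT arsenite 6 h replicate 2). HMOX1 reached 2310 ± 448 against 190 ± 28.1, and the ferritin light chain FTL 3170 ± 215 against 1220 ± 41.6. Metallothioneins had 2 of 5 higher (median 2.17, adjusted p = 0.014, adjusted p = 0.18 with an estimated correlation).

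Histone, ribosomal protein and zinc finger mRNAs also stood higher with arsenite than without at 6 h, a comparison that shares the untreated 6 h libraries with the WT chase, with opposite sign, and is thus not independent of it. Histones had 42 of 50 higher (43 adjusted over the list alone, median 2.42, camera adjusted p = 5e-19, adjusted p = 0.056 with an estimated correlation). Ribosomal proteins had 64 of 78 higher (69 adjusted over the list alone, median 0.85, adjusted p = 1.3e-16, but adjusted p = 0.19 with an estimated correlation). RPS28 stood at 687 ± 15.4 against 207 ± 116 and FAU at 1710 ± 33.9 against 409 ± 181. ZNF genes had 206 of 448 higher and 17 lower (227 and 18 adjusted over the list alone, median 0.78, adjusted p = 1.1e-05 with an estimated correlation). The nuclear-encoded respiratory chain had 23 of 75 higher and 5 lower (25 and 5, median 0.59, adjusted p = 0.00071, but adjusted p = 0.4 with an estimated correlation). Cholesterol synthesis had 6 of 22 higher and 2 lower (8 and 2, median 0.63, adjusted p = 0.014, but adjusted p = 0.19 with an estimated correlation). INSIG1 stood at 4520 ± 261 against 1060 ± 152. Mitochondrially encoded mRNAs instead had 6 of 12 lower and 0 higher (6 adjusted over the list alone, median −0.41, adjusted p = 0.00088, but adjusted p = 0.18 with an estimated correlation), with MT-CO3 at 5000 ± 269 against 14100 ± 96.

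**Figure D3:**
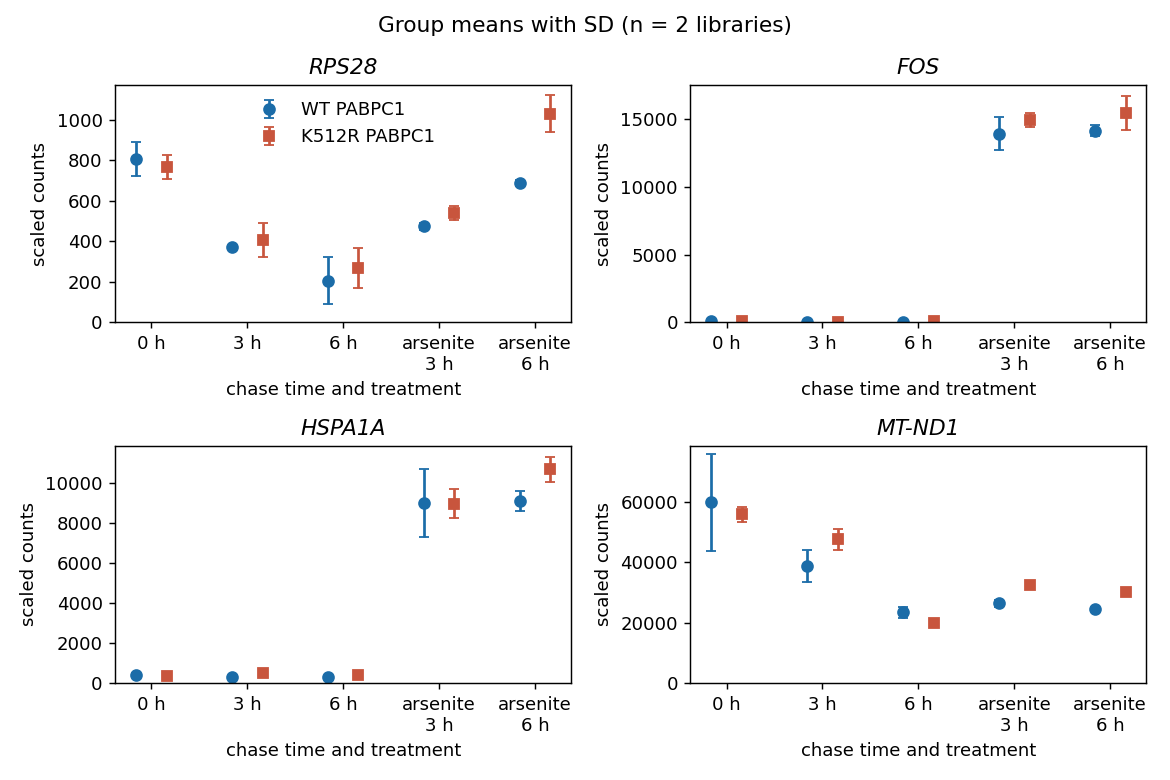
Group means with SD (error bars, 2 libraries) in scaled counts (vertical axes) of RPS28, FOS, HSPA1A and MT-ND1, by chase time and treatment (horizontal axes), with circles for WT and squares for K512R. RPS28 in WT goes from 806 at 0 h to 207 at 6 h without arsenite and is at 687 at 6 h with it, and FOS is at 14100 with arsenite.

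Against the 0 h libraries in place of the untreated 6 h ones, the WT arsenite chase at 6 h called 1728 genes, 802 higher and 926 lower. On that comparison 29 of 35 immediate early and AU-rich element mRNAs (32 adjusted over the list alone, median 2.16, adjusted p = 2.8e-05 with an estimated correlation) and 20 of 23 heat shock genes (median 1.38, adjusted p = 0.00017 with an estimated correlation) were higher. Ribosomal proteins had 6 lower and 0 higher (median −0.23), histones 2 higher (median 0.29) and ZNF genes 22 higher and 29 lower (median −0.06). Of 12 mitochondrially encoded mRNAs 11 were lower (median −1.38, adjusted p = 0.0016 with an estimated correlation).

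The mitophagy list did not move as a group with arsenite in WT cells, with 5 of 39 members higher and 8 lower at 6 h (6 and 8 adjusted over the list alone, median 0, adjusted p = 0.66). MUL1 was higher (542 ± 36.7 against 158 ± 8.34, log2 difference 1.77, SE 0.25, limma adjusted p = 3.9e-05) and RHOT1 lower (223 ± 4.76 against 565 ± 32.1, −1.34, SE 0.31, adjusted p = 0.0033). Stress granule components had 8 of 35 higher and 14 lower (9 and 14 adjusted over the list alone, median −0.14, adjusted p = 0.14). G3BP1 was lower (10700 ± 316 against 20800 ± 774, −0.95, SE 0.10, adjusted p = 7.1e-07), while NUFIP2 (10100 ± 760 against 5290 ± 478) was higher. Autophagy core machinery had 5 of 38 higher and 2 lower (adjusted p = 0.66), led by GABARAPL1 (2820 ± 94 against 1290 ± 222) and MAP1LC3B (5060 ± 260 against 2610 ± 258). The PABP and SUMO pathway had 4 of 26 higher and 1 lower (adjusted p = 0.66), including PABPC4 at 3730 ± 114 against 2690 ± 112. Among the mRNA decay genes 9 of 43 were higher and 8 lower (adjusted p = 0.9), with TOB1 at 2330 ± 18.6 against 399 ± 106 and the deadenylase CNOT6L at 932 ± 173 against 1950 ± 141. G2/M genes (6 of 32 higher, 9 lower, adjusted p = 0.38), glycolysis (4 of 18 higher, adjusted p = 0.61), the secretory list (3 of 26 higher, 6 lower, adjusted p = 0.42) and fibroblast markers (0 of 6, adjusted p = 0.9) were not called. Of the haematopoietic markers, CD68 was lower at 77 ± 45.8 against 197 ± 11.7 (adjusted p = 0.032), a call lost without WT 6 h replicate 1 (0.13) or 2 (0.09) or WT arsenite 6 h replicate 2 (0.32).

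In total limma called 4269 genes in WT cells at 6 h with arsenite, 2378 higher and 1891 lower, of which 2307 differed at least 2-fold. Without any 1 of the 4 libraries the count was 3014 to 3510, and over genes in a locus of their own 2658. The largest falls went from 55.2 to 160 scaled counts to about 0 (RASGRP1, 75.2 ± 18.5 without arsenite, adjusted p = 0.0056; SPHAR, GATS, RP11-603J24.9 and TMEM163, which lie in shared loci). The calls of SPHAR, GATS and TMEM163 were lost without any 1 library (adjusted p = 0.051 to 0.096).

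In K512R cells at 6 h, heat shock and immediate early mRNAs were among those higher with arsenite. HSPA1A stood at 10700 ± 624 scaled counts against 393 ± 8.96 (log2 difference 4.76, SE 0.20, limma adjusted p = 1.8e-11) and its co-chaperone DNAJB1 at 34700 ± 4000 against 1470 ± 35.6 (4.55, SE 0.17, adjusted p = 1e-11). MT1X stood at 6400 ± 178 against 122 ± 6.94 (5.71, SE 0.23, adjusted p = 1.1e-11) and DDIT3 at 2950 ± 212 against 110 ± 24.4 (4.76, SE 0.26, adjusted p = 3.6e-10). EGR3 (480 ± 5.6 against 0.44 ± 0.622), EGR2, HSPA6, FOS (15400 ± 1240 against 71.1 ± 92.2) and ARC (245 ± 44.3, listed at 0 without arsenite) were the largest rises. MT-ND1 was higher with arsenite at 30000 ± 271 against 19700 ± 465 (0.60, SE 0.14, adjusted p = 0.0033, or 0.05 with library quality weights), and MT-CO3 lower at 6230 ± 543 against 11100 ± 1820 (−0.83, SE 0.13, adjusted p = 6.3e-05).

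In K512R cells 34 of 35 immediate early and AU-rich element mRNAs (34 adjusted over the list alone, median 3.08, adjusted p = 9e-05 with an estimated correlation) and 19 of 23 heat shock genes (19, with 1 lower, median 1.54, adjusted p = 0.0057 with an estimated correlation) were higher. Also higher were 14 of 20 integrated stress response targets (15, median 1.6, camera adjusted p = 2.5e-08, adjusted p = 0.067 with an estimated correlation) and 42 of 50 histones (43, median 2.64, adjusted p = 4.1e-19, adjusted p = 0.056 with an estimated correlation). Of 78 ribosomal proteins 60 were higher (63, median 0.89, adjusted p = 4e-15, adjusted p = 0.2 with an estimated correlation). This comparison shares the untreated 6 h libraries with the K512R chase, with opposite sign, and is thus not independent of it. In replicate 2 of that untreated group, ribosomal proteins stood below replicate 1 by a median of 0.65 log2 units and histones by 0.52. ZNF genes had 212 of 448 higher and 23 lower (222 and 24, median 0.77, adjusted p = 5.3e-05 with an estimated correlation). Mitochondrially encoded mRNAs had 2 of 12 higher and 2 lower (3 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.83). Mitophagy genes had 11 of 39 higher and 9 lower (12 and 10, median −0.06, adjusted p = 0.51), with MUL1 at 664 ± 67.3 against 184 ± 58. Stress granule components had 6 of 35 higher and 14 lower (8 and 14, median −0.11, adjusted p = 0.038, but adjusted p = 0.067 with an estimated correlation, 0.66 with quantile normalization, 0.066 without K512R 6 h replicate 1 and 0.11 without K512R arsenite 6 h replicate 1). G3BP1 stood at 11000 ± 699 against 20800 ± 2540. The monocyte marker CD14 stood at 91.7 ± 37.1 with arsenite and was listed at 0 without (adjusted p = 0.0056, or 0.067 with library quality weights).

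There were 4916 calls in this comparison, 2775 higher and 2141 lower (2141 and 2517 with quantile normalization, which removes a shift of 0.11 in the median gene). Both lines had 1779 genes called higher in each (439 by chance) and 1463 called lower in each (269 by chance), and 8 in opposite directions, with r = 0.53 across all genes and 0.86 over those with a mean of at least 100. The chance values have the same limit as in the chase. Replicate 2 of the K512R arsenite 6 h group stood apart on the third principal component (139.1 against −36.5 for replicate 1), and without it 4005 genes were called. In a fit of the 4 libraries alone 2283 genes were called, with library quality weights 3018, and over genes in a locus of their own 3055. LIN7A, PALM2-AKAP2, TICAM2, RP11-603J24.9 and PCDHA12, all in shared loci, were the largest falls, and the call of TICAM2 was lost without K512R 6 h replicate 2 (adjusted p = 0.092) or either arsenite library (0.06 and 0.065).

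Whether K512R changed the response was tested as the difference between the lines in their change over time, and few genes passed. For the mitophagy receptor SQSTM1 the difference of responses was −0.22 in the 6 h chase (SE 0.26), −0.09 and 0.04 in the arsenite chase at 3 and 6 h, and 0.26 for arsenite against no arsenite at 6 h. The ubiquitin ligase HUWE1 gave values from −0.18 to 0.00 (SE 0.15), G3BP1 from −0.16 to 0.03 (SE 0.14) and the chaperone HSPA8 from −0.14 to 0.26 (SE 0.14). In the contrast of arsenite at 6 h, 3 genes were called, all lower in K512R. The lysosomal transporter gene DIRC2 (chromosome 3, 122513642 to 122600320, plus strand) went from 382 ± 105 to 17.3 ± 15.2 with arsenite in K512R and from 149 ± 23.6 to 181 ± 8.18 in WT cells (log2 difference −5.01, SE 0.75, limma adjusted p = 0.018). LIN7A went from 164 ± 76.8 to about 0 in K512R and from 107 ± 45.5 to 82.8 ± 49.2 in WT cells (−7.84, SE 1.03, adjusted p = 0.0085). AGBL3 went from 35.8 ± 14 to being listed at 0 in K512R and from 17.3 ± 4.71 to 78.9 ± 26.9 in WT cells (adjusted p = 0.0085).

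Of 15028 genes, limma called 0 in the genotype by chase contrast at 6 h (490 with an unadjusted p under 0.05, 751 by chance), 0 in the genotype by arsenite chase contrast at 3 h (398) and 0 at 6 h (926), and 3 in the genotype by arsenite contrast at 6 h (1130). The 3 calls were lost in a fit of the 8 libraries alone (0 called) and with library quality weights (0 called), and LIN7A and AGBL3 lie in shared loci. All 3 were lost without K512R 6 h replicate 2 (adjusted p = 0.05 to 0.068), and AGBL3 (0.054) and DIRC2 (0.087) also without WT 6 h replicate 1. Leaving out K512R 6 h replicate 1 gave 233 calls in that contrast and 73 in the genotype by chase contrast, whereas leaving out replicate 2 gave 1 and 2. Leaving out K512R arsenite 6 h replicate 1 gave 32 calls in the genotype by arsenite contrast and 28 in the arsenite chase contrast at 6 h. Leaving out replicate 2 of that group, which stood apart on the third principal component, gave 10 and 11. Comparing the lines directly, limma called 0 genes at 3 h (593 unadjusted), 0 at 6 h (600), 0 with arsenite at 3 h (462) and 14 with arsenite at 6 h (6 higher and 8 lower in K512R, 1490 unadjusted). The median 95% interval of a difference of responses reached 1.17 log2 units to each side.

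Among gene lists, neither mitophagy (camera adjusted p = 0.76 to 0.92) nor stress granule components (0.39 to 0.99) differed between the lines in any of the 4 contrasts. Mitochondrially encoded mRNAs were the list with most calls, though the 4 contrasts share libraries and are not independent. In the genotype by arsenite contrast at 6 h all 12 members had a positive value (median 0.58, adjusted p = 1.1e-07, 0 called over all genes and 6 adjusted over the list alone), with an adjusted p = 0.11 with an estimated correlation. MT-ND1 went from 19700 ± 465 to 30000 ± 271 in K512R and from 23400 ± 1920 to 24400 in WT cells (log2 difference 0.54, SE 0.20, limma adjusted p = 0.56). The list was also shifted by −0.28 in the genotype by chase contrast (adjusted p = 0.0043, adjusted p = 0.59 with an estimated correlation). Its shift was 0.35 in the arsenite chase at 3 h (adjusted p = 1e-04, adjusted p = 0.4 with an estimated correlation) and 0.35 at 6 h (adjusted p = 0.0081, adjusted p = 0.9 with an estimated correlation). The list lost its call without single libraries in 3 of these contrasts, in the genotype by chase one for instance without WT 0 h replicate 2 (−0.16, adjusted p = 0.73). The arsenite chase medians came down to 0.09 and 0.04 without WT 0 h replicate 1. Heat shock genes were shifted by 0.23 in the genotype by chase contrast (adjusted p = 2.8e-05, adjusted p = 0.26 with an estimated correlation). The respiratory chain was shifted by 0.19 in the genotype by arsenite contrast (adjusted p = 0.0084, adjusted p = 0.87 with an estimated correlation, and 0.57 without K512R 6 h replicate 2).

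**Figure D4:**
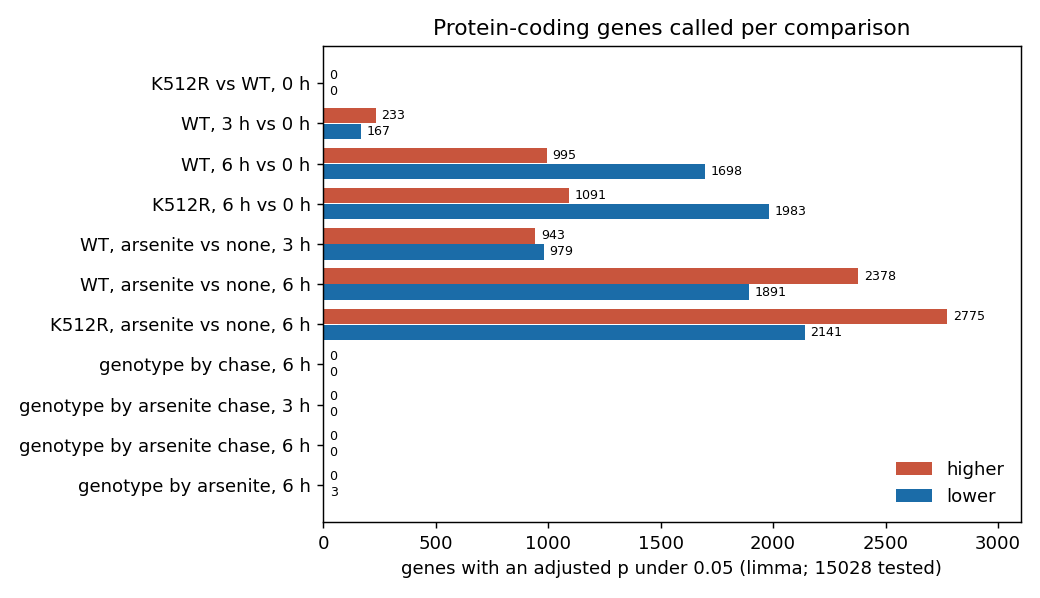
Number of protein-coding genes with a limma adjusted p under 0.05 (horizontal axis) per comparison (vertical axis), split into higher and lower. The chase and arsenite comparisons call 400 to 4916 genes, and K512R against WT at 0 h and the 4 contrasts of the response between the lines 0 to 3. Direct comparisons of the lines at other times are not shown.

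Long non-coding RNAs were followed as 11450 transcripts, many of which overlap each other or a protein-coding gene, so that the division of reads between them is uncertain. Their values were noisier: the median 95% interval of a pairwise difference reached 3.27 log2 units to each side. During the WT chase to 6 h, host RNAs of small nucleolar RNAs fell. SNHG1 (ENST00000538654) went from 1800 ± 283 to 337 ± 32.2 scaled counts (log2 change −2.41, SE 0.17, limma adjusted p = 6.4e-06) and GAS5 (ENST00000431268) from 625 ± 252 to 110 ± 14 (−2.45, SE 0.34, adjusted p = 0.002). The nuclear KCNQ1OT1 (NR_002728) fell from 782 ± 13.1 to 268 ± 19.9 (−1.55, SE 0.18, adjusted p = 0.00055). LINC00657 (ENST00000565493), a cytoplasmic RNA also known as NORAD, rose from 16100 ± 1000 to 24500 ± 1280 (0.60, SE 0.07, adjusted p = 0.00055). NEAT1 (uc010rog.2, chromosome 11, 65184126 to 65213011, plus strand), the scaffold of paraspeckles, went from 2890 ± 1300 to 9270 ± 2210 (1.74, SE 0.35, adjusted p = 0.03, or 0.24 without WT 0 h replicate 2 and 0.2 without WT 6 h replicate 1).

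In that chase 71 transcripts were called, 16 higher and 55 lower (30 and 38 with quantile normalization), of which 3 and 15 overlapped the exons of another gene on the same strand. Of 166 snoRNA host transcripts 8 were lower (12 adjusted over the list alone, median −1.17, camera adjusted p = 1.4e-05, adjusted p = 0.0049 with an estimated correlation). Nuclear lncRNAs had 1 of 54 higher and 2 lower (median 0, mean 0.18, test upward, adjusted p = 0.049, or 0.14 with quantile normalization, 0.14 without WT 0 h replicate 1 and 0.3 without WT 6 h replicate 2). Cytoplasmic lncRNAs had 1 of 39 higher (median 0, mean −0.04, test upward, adjusted p = 0.024, or 0.12 without WT 0 h replicate 1 and 0.11 without WT 6 h replicate 1). The 2 lower nuclear members were both transcripts of KCNQ1OT1, with nearly the same values (783 and 782 scaled counts at 0 h). The 3 lists hold 25, 11 and 11 genes, whose transcripts can share reads, so their members are not independent. The lists' calls in the chase all held with an estimated correlation. For the nuclear and cytoplasmic lists that estimate was −0.005 and −0.009, below the preset 0.01, so it allowed for no dependence between members. With fry both had an adjusted p = 0.83, against 0.00036 for the snoRNA hosts. A fit of the 4 libraries alone called 0 transcripts, which also ended the calls named above (adjusted p = 0.24). Among the largest changes, AF088041 (uc003fwf.1) rose from 0.2 ± 0.271 to 380 ± 53.8, and CSRNP2 (NR_045072), FGD5-AS1 (ENST00000426200), KLF10 (NR_103760) and AK054845 (uc001uoi.3) went from 71.2 to 229 scaled counts to about 0.

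With arsenite at 6 h, KCNQ1OT1 stood at 2470 ± 20.8 against 268 ± 19.9 scaled counts without (log2 difference 3.21, SE 0.18, limma adjusted p = 6.5e-08) and the host transcript SNHG7 (ENST00000447221) at 373 ± 25.5 against 20.3 ± 0.896 (4.17, SE 0.58, adjusted p = 0.00078). RP11-16N11.2 (ENST00000566372, chromosome 3, 160471216 to 160472930, minus strand), a bidirectional transcript, reached 527 against 0.349 ± 0.493 (9.41, SE 0.67, adjusted p = 8.6e-07). OIP5-AS1 (ENST00000500949) was lower at 1060 ± 11.9 against 3740 ± 574 (−1.81, SE 0.24, adjusted p = 0.00047), as was LINC00657 at 13700 ± 629 against 24500 ± 1280 (−0.84, SE 0.07, adjusted p = 4.4e-06, or 0.073 with quantile normalization). Of 508 calls 383 were higher and 125 lower (252 and 180 with quantile normalization). Bidirectional transcripts had 70 higher and 2 lower, natural antisense transcripts 58 and 3 and intergenic ones 144 and 38, and those overlapping exons on the same strand 48 and 52. SnoRNA hosts had 20 of 166 transcripts higher (27 adjusted over the list alone, median 0.95, camera adjusted p = 0.00031, adjusted p = 0.014 with an estimated correlation). Nuclear lncRNAs had 6 of 54 transcripts higher, KCNQ1OT1 counting more than once, and 2 lower (adjusted p = 0.77). Cytoplasmic lncRNAs had 2 of 39 transcripts lower (adjusted p = 0.11). The largest falls (NFAT5 uc002exo.2, CTB-89H12.4 ENST00000412431, APLP2 NR_024515 and AL832937 uc021ogn.1) all overlapped exons of another gene on the same strand. A fit of the 4 libraries alone called 2 transcripts, and the count was 275 without WT 6 h replicate 1 and 313 without replicate 2.

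Between the lines at 0 h, no lncRNA of the 3 lists was called. MALAT1 (ENST00000544868) stood at 71200 ± 1860 scaled counts in K512R and 69000 ± 12400 in WT cells (log2 difference 0.06, SE 0.12) and NEAT1 at 4120 ± 257 and 2890 ± 1300 (0.59, SE 0.35). In all, 18 transcripts were called by limma, 4 higher and 14 lower in K512R (12 and 10 with quantile normalization). The largest were AF088041 (428 ± 398 against 0.2 ± 0.271, adjusted p = 0.0011), ZNF75A (NR_126069), AGO1 (uc009vuy.3, about 0 against 184 ± 73.2, adjusted p = 0.00042), KLF10 (NR_103760) and UHRF1 (ENST00000587870). The last 4 overlap exons of their gene on the same strand, and when values were summed per locus 2 calls were made, and in a fit of the 4 libraries alone 0. Without K512R 0 h replicate 2 there were 67. None of the 3 lncRNA lists was called at 0 h (camera adjusted p = 0.71 to 0.79) or in the genotype by arsenite chase contrast at 6 h (0.93). In that contrast limma called 23 transcripts, 12 higher and 11 lower (772 unadjusted, 572 by chance), 7 when summed per locus and 0 in a fit of the 8 libraries alone. The count was 4 without K512R 0 h replicate 1 and 108 without K512R arsenite 6 h replicate 1. NEAT1 stood at 44500 ± 6540 with arsenite against 4120 ± 257 at 0 h in K512R and at 50400 ± 3420 against 2890 ± 1300 in WT cells (difference −0.77, SE 0.49, adjusted p = 0.84).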

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

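The tests of explanations in this part were chosen after the results had been seen. What drew attention to the results of this paragraph and the next was a tested difference between the 2 lines in their response. In the genotype by arsenite contrast at 6 h limma made 3 calls, LIN7A (−7.84), DIRC2 (−5.01) and AGBL3 (−8.27, listed at 0 in K512R cells with arsenite, so that the size has no bound), and the nuclear-encoded respiratory chain list had a median of 0.19 (adjusted p = 0.87 with an estimated correlation, and 0.57 without K512R 6 h replicate 2). The heat shock list had a median of 0.23 in the genotype by chase contrast (adjusted p = 0.26 with an estimated correlation). In the genotype by arsenite chase contrast at 6 h 23 lncRNA transcripts were called, among them KDM2B (uc001uap.3, 14.78), AGO1 (uc009vuy.3, 10.43), RP4-769N13.6 (ENST00000475738, 10.12), LINC00969 (ENST00000429897, 9.94), AF088041 (uc003fwf.1, −8.89), ICA1L (uc021vvi.1, −7.8), XLOC_003528 (TCONS_00008781, −6.69) and THAP9-AS1 (ENST00000504520, −6.14). The values of KDM2B, RP4-769N13.6 and LINC00969 are differences of fitted values with no bound, since each was listed at 0 in K512R at 0 h and in WT with arsenite. Those of LIN7A, AGO1, AF088041, ICA1L and XLOC_003528 rest on a group listed at about 0, so that the pseudocount of 0.5 sets their size. AF088041 was at about 0 with arsenite in both lines, so its value is in essence its 0 h difference (8.91) with the sign turned. AGO1 likewise already differed between the lines at 0 h (−8.46), in the same 0 h libraries.

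The list of mitochondrially encoded mRNAs was called between the lines in 4 contrasts at the preset correlation and in none with an estimated correlation, with medians of −0.28 (genotype by chase, 6 h, adjusted p = 0.59 with an estimated correlation), 0.35 (genotype by arsenite chase, 3 h, 0.4), 0.35 (the same at 6 h, 0.9) and 0.58 (genotype by arsenite, 6 h, 0.11). These 4 contrasts are not independent, as the last is the third minus the first and the first 3 share the 0 h libraries. The 2 arsenite chase medians fell to 0.09 and 0.04 without WT 0 h replicate 1. For the last, a division of reads among the 12 mRNAs cannot change their sum. That sum still gave 0.47 (SE 0.21), with an unadjusted p = 0.041 from limma, 1 of 17 contrasts computed. A division with RNA outside the 12 stays open, as the sum cannot test it. MT-ND1 and MT-CO1, listed in loci of their own, had whole-read values in only 1 and 5 of the 20 libraries. Other high genes in loci of their own also had few, such as MKI67 (7) and HSPA8 (8). These counts therefore cannot show whether mitochondrial reads were divided. K512R 6 h replicate 2 alone does not account for the list median of that contrast, which was 0.58 without this library. Whether the substitution itself lies behind the difference stays open, since each genotype is a single line.

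Stress mRNAs of the arsenite chase lay above their own level at 0 h, before arsenite was added. In WT cells 10 genes, among them CXCR4, EGR2 and HSPA6, were under 20 scaled counts in both 0 h libraries and over 200 in both arsenite libraries at 6 h, against 8 in K512R cells and 0 without arsenite. An earlier version of this count, with a mean under 20 at 0 h, had given 12, 13 and 0. This fits RNA made during the chase entering the captured pool, though whether it was labelled by remaining 4sU or carried through the capture unlabelled cannot be told. Stabilisation of RNA made before the chase stays open for the rest, as the immediate early list's median of 2.16 against 0 h depends on the size of the pool, which was not measured.

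K512R 6 h replicate 2 stood apart from replicate 1. RNA from an arsenite sample in it stays open for the stress mRNAs, at a median excess of 0.84% of the arsenite level in 9 genes, a set narrowed after 51 genes had given 0.35% with 24 of them negative. It does not account for the difference over all genes, whose median was 0.34 after that share was taken out, and lower depth does not either (12.35 M reads against a median of 11 M). A chase further along stays open: genes higher in the WT chase exceeded those lower in it by 0.36 in this library, but zinc finger genes, a family first picked after family medians were seen, gave 0.03 where a fall would have been the sign. No biological explanation was tested, as both libraries carry the same label.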

How the results depend on the processing

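Library quality weights, filters at 20 scaled counts, loci and overlap classes were chosen as alternatives after results were seen. Of 150 counts of calls under other settings 117 stayed within 1.5 times, and of 80 with 1 library left out 37 did. Of 291 results for named genes, each a gene in a single comparison, 77 changed side of the threshold under some other setting (75 weaker, 2 stronger) and none reversed. Of 100 list results 32 changed, 26 of them with an estimated correlation. With 1 library left out, 72 of the gene results and 13 of the list results changed side. The list of stress granule components in the WT chase at 6 h reversed, from 0.04 to −0.1, with quantile normalization, and the cause was not tested. Not run were the alternatives on 3′ UTR uridine content. What depth limits was not tested by level. Of the simulated 2-fold changes, all at a mean of at least 20 scaled counts, 40% were recovered in the WT arsenite comparison at 6 h for genes and 0% for lncRNAs. Far fewer genes were changed in the simulation than the 4269 called in the data, so the share for genes may differ there.

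With a pseudocount of 0.1 the genotype by arsenite chase contrast at 6 h went from 0 to 2 calls, and lncRNA K512R against WT at 0 h from 18 to 30. With no filter the lncRNA counts were 40 (0 h), 113 (WT chase, 71 before) and 79 (genotype by arsenite chase, 23 before). In a fit of only the libraries compared the WT chase at 3 h gave 753 calls (400 before), the K512R chase 1174 (3074), WT arsenite at 3 h 2938 (1922), K512R arsenite 2283 (4916) and genotype by arsenite 0 (3). For lncRNA it gave 0 at 0 h, 0 in the chase, 2 with arsenite (508) and 0 in genotype by arsenite chase. With library quality weights the counts were 1421 (WT chase, 3 h), 3282 (WT arsenite, 3 h), 3018 (K512R arsenite), 0 (genotype by arsenite), 114 (lncRNA chase) and 12 (lncRNA genotype by arsenite chase). At 20 scaled counts, genotype by arsenite chase at 6 h gave 2 calls, lncRNA 0 h 3 and lncRNA genotype by arsenite chase 9. Over genes in a locus of their own, where fewer genes are tested, counts were 1682 (WT chase, 6 h), 1913 (K512R chase), 1259 (WT arsenite, 3 h), 2658 (WT arsenite, 6 h), 3055 (K512R arsenite) and 1 (genotype by arsenite). Summed per locus, lncRNA calls were 2 at 0 h and 7 in genotype by arsenite chase, which had 6 without transcripts overlapping exons. Except where fewer genes were tested, the cause was not tested.

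With the replicate number as a block, lncRNA calls in genotype by arsenite chase went from 23 to 15, and the other 14 counts fitted this way stayed within 1.5 times (for instance 2570 in the WT chase at 6 h). Direct comparisons of the lines after 0 h and of the arsenite chase with 0 h were not run under other settings. No clear pairing by number was seen: deviations of same-numbered libraries correlated at −0.09 to 0.16 over 45 pairs of groups, median 0. All tested genes entered these values, low and noisy ones too, so that a pairing is not excluded.

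With 1 library left out, whose partner is then assumed to vary like the other groups, counts ranged from 0 to 9 (K512R against WT, 0 h), 49 to 181 (WT chase, 3 h), 1487 to 2150 (WT chase, 6 h), 1527 to 4144 (K512R chase), 962 to 1249 (WT arsenite, 3 h), 3014 to 3510 (WT arsenite, 6 h), 3346 to 5342 (K512R arsenite), 0 to 73 (genotype by chase), 0 to 1 and 0 to 28 (genotype by arsenite chase, 3 and 6 h) and 1 to 233 (genotype by arsenite). For lncRNA they ranged from 22 to 67 (0 h), 68 to 93 (chase), 275 to 491 (arsenite) and 4 to 108 (genotype by arsenite chase).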

Other observations

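The comparisons in this part were chosen after the results had been seen. Mitochondrially encoded mRNAs made up 3.15 ± 0.64% of protein-coding scaled counts in WT cells at 0 h, 1.53 ± 0.11% at 6 h and 1.14 ± 0.01% at 6 h with arsenite (mean ± SD, 2 libraries), and in K512R cells 2.96 ± 0.1%, 1.28 ± 0% and 1.33 ± 0.07%.

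Across 5592 genes in a locus of their own with a mean of at least 100, the span of the locus correlated with the log2 change at 6 h of chase at a Spearman rho of 0.4 in WT and 0.44 in K512R cells, and with the arsenite difference in WT cells at −0.39. With the genes ranked by span into 4 sets of 1398 the median WT chase changes were −0.57, −0.17, 0.07 and 0.12, from the shortest (median 9.56 kb) to the longest (164 kb), and the median arsenite differences 0.53, 0.07, −0.2 and −0.29. Genes are not independent replicates, and the WT chase and arsenite comparisons share the WT 6 h libraries with opposite sign.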
